A study of Danio rerio with 8 samples.

How the data were processed

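The deposited data were 8 matrices of UMI counts per gene and cell barcode, 1 per library, as whole numbers with no normalization. Per the labels, libraries were made with the 10x Genomics 3' v2 chemistry from papain-dissociated zebrafish retina, and Cell Ranger and Seurat were named as the authors' processing tools. Genome build, annotation and software versions are not given in the sources used here. The matrices held 28951 genes and 35791 barcodes, from 1700 (14 dpf replicate 1) to 6508 (24 hpf) per library. Gene symbols were taken from the deposited gene tables, where 934 genes share a symbol with another gene and 686 carry only their identifier. A symbol shared by several genes is given with its identifier where a value is printed for 1 of them. The replicates of a stage were not copies of each other, since their summed counts differed far beyond counting error (chi-square per degree of freedom of 133.6 at 48 hpf, 67.1 at 72 hpf and 201.4 at 14 dpf). Replicate 2 of 48 hpf was deposited much later than the other libraries, and no label gives a sequencing batch or date.

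Barcodes with fewer than 400 genes (1) or more than 20% mitochondrial UMIs (2) were removed, as were 1444 predicted doublets, set per library at a rate that grew with its number of cells, by comparison with simulated doublets among 30 neighbours. The doublets were left out of the class sums and shares only, which left 34344 cells there. Clustering and the naming of clusters used 35788 cells, doublets included. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 40 principal components, libraries were integrated with a reimplementation of Harmony (theta 0.5, 50 clusters, 10 rounds), and cells were clustered by the Leiden method (20 neighbours, resolution 1) into 37 clusters. Clusters were named by the mean score of 18 marker lists, with no cell moved by hand. Those with fewer than 3 markers detected, none among their top 10 genes, or more markers of another class there stayed unnamed. Software was python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Several of these choices were made after the first clusters were seen. A first clustering of all cells gave 41 clusters, from which 3332 cells of clusters with a score of at least 1.2 for a class outside the neural retina were set aside, the rest being integrated and clustered again. The Harmony theta, this score and the naming thresholds were also set at that point. Marker genes of a class took part in naming its clusters, so their change within a class is conditional on that naming, and the marker lists share cell cycle and neurogenic genes with the function lists.

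UMI counts were summed per library and class where at least 20 cells were present. Sums were compared with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. Progenitors and precursors were fitted over the 6 libraries of 48 hpf, 72 hpf and 14 dpf with stage as a factor, and photoreceptors, amacrine, bipolar and ganglion cells over the 4 libraries of 48 and 72 hpf. The step from progenitor to precursor was compared between 14 dpf and the mean of 48 and 72 hpf by an interaction term with library as a block. Log2 folds are given with the standard error implied by the F statistic, as ± SE, unless marked SD. Every adjusted p for a gene comes from edgeR unless DESeq2 is named. Unadjusted p-values, two-sided, are counted only beside counts of 0 or few calls. The 19 function lists and 18 marker lists were tested by camera in limma 3.58.1 (correlation preset to 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation. A number "adjusted over the list alone" comes from the Benjamini-Hochberg method within the list. Progenitors of 24 and 36 hpf, with 1 library each, were compared by ratios of CPM with 95% exact Poisson intervals and by list medians against 10000 random lists matched in 20 expression bins. Progenitor sums were also compared by the root mean square difference of log2 (CPM + 1).

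The gene and marker lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from the choices named above. The rule took the 6 largest log2 folds each way among called genes with a mean of at least 20 CPM and one direction in every pair of libraries, the 3 members with the smallest adjusted p from each list that passed, and 15 progenitor and neurogenic genes in every progenitor or precursor comparison. For 36 against 24 hpf it took the 8 largest ratios each way among genes with at least 50 CPM. Where the rule gave many list members, part of them were printed, and the rest are in the counts. The results of some genes that the rule chose are not reported here. CPM of arr3a and cebpd across classes, and the cluster shares, were chosen for printing after their values were seen.

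The edgeR fits were tested on simulated data built from the same sums with 200 genes changed. The changed genes were drawn from those with a mean of at least 20 CPM, and all stages were given the same spread. The rates therefore do not cover lower genes or a stage whose libraries vary more. Among 4-fold changes, 96% to 100% were recovered in progenitors, 89% in precursors, 100% for the interaction, and 79%, 45%, 69% and 83% in photoreceptors, amacrine, bipolar and ganglion cells. Among 2-fold changes, 25% to 32% were recovered in progenitors, 17% and 18% in precursors, 76% for the interaction, and 12%, 0%, 6% and 12% in the other classes in that order, with at most 7.8% false calls. Alternatives were DESeq2 1.42.0, RLE normalization, no low-count filter, sums thinned to the smallest total, genes far below the all-cell level left out, at least 800 genes per cell, doublets kept, clustering resolution 2, fits of 4 libraries, a single embryonic stage as the reference, leaving out each library, and, chosen after seeing the data, a Harmony theta of 1 (stronger integration), unnamed clusters joined to their best-scoring class, and the largest cluster of a class alone. Horizontal cells, Müller glia and cells of other tissues were not among the planned comparisons between stages.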

Results

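Retinal cells of the zebrafish (Danio rerio) were profiled by droplet-based 3' single-cell RNA sequencing in 8 libraries. There was 1 library at 24 hours post fertilization (hpf), 1 at 36 hpf and 2 each at 48 hpf, 72 hpf and 14 days post fertilization (dpf). The embryonic and larval libraries up to 72 hpf came from dissociated whole retina of the AB strain. At 14 dpf, GFP-positive cells were sorted from fish carrying PCNA-GFP, a reporter of proliferating cells, with the ciliary marginal zone (CMZ), the growing rim of the retina, as the labelled tissue. Total deposited UMI counts ranged from 10375181 (14 dpf replicate 1) to 92548127 (24 hpf), and median UMIs per cell ranged from 4141.5 (72 hpf replicate 2) to 13661 (24 hpf). All comparisons of 14 dpf with earlier stages also compare sorted with unsorted cells, transgenic with wild-type fish and the margin with the whole retina. The transgene is given by the protocol text, while the genotype label of the 14 dpf fish reads wildtype. The labels do not say whether replicates came from separate animals, so p-values of single genes measure only the spread between these libraries. The p-values of lists, by camera, set the genes of a list against the other genes. They depend on the number of genes and on the correlation preset or estimated between them.

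Cycling progenitors were the main class at the first stages and were outnumbered by differentiating neurons at 48 and 72 hpf. Progenitors, which express pcna, mki67 and ccnd1, made up 65.3% of cells at 24 hpf (95% exact Clopper-Pearson interval 64.1 to 66.5) and 44.2% at 36 hpf (42.9 to 45.5). Their share was 10.7% ± 4.32 (SD, n = 2) at 48 hpf, 8.39% ± 0.858 (n = 2) at 72 hpf and 17.0% ± 14.7 (n = 2) at 14 dpf. Neurogenic precursors, marked by atoh7, neurod4 and hes6, were 2.25% of cells at 24 hpf (1.90 to 2.66) and 12.4% at 36 hpf (11.5 to 13.2). Their share was 11.1% ± 4.34, 6.36% ± 2.65 and 17.9% ± 12.5 at 48 hpf, 72 hpf and 14 dpf. No retinal ganglion cell was found among 6169 cells at 24 hpf, which allows a share of up to 0.0486%. Ganglion cells, the first retinal neurons to be born, were 1.38% at 36 hpf (1.1 to 1.71), 7.65% ± 0.129 at 48 hpf and 13.2% ± 4.18 at 72 hpf. Amacrine cells, the inhibitory interneurons, were 19.5% ± 2.69 at 48 hpf and 24.5% ± 6.46 at 72 hpf, and photoreceptors were 11.3% ± 3.13 and 18.6% ± 6.36. Bipolar cells ranged from 5.66% in replicate 1 to 23.0% in replicate 2 at 48 hpf. Horizontal cells held 4.24% and 5.16% of cells, and Müller glia 1.74% and 1.92%, at 48 and 72 hpf. The replicates at 14 dpf differed widely, with 6.56% progenitors and 24.4% amacrine cells in replicate 1 against 27.4% and 2.67% in replicate 2. Cells of other tissues were present too, including lens cells (6.84% at 24 hpf, 2.90% at 36 hpf, 4.23% and 4.60% at 14 dpf). A cluster with forebrain markers held 14.2% of cells at 36 hpf and stayed unnamed at the finer clustering resolution. Clusters left unnamed held 16.1% and 15.6% of cells at 24 and 36 hpf, 18.4% ± 1.85 at 48 hpf, 10.9% ± 3.57 at 72 hpf and 15.6% ± 8.11 at 14 dpf. At the finer resolution, an unnamed cluster led by her12 and her4.1 (8.79% of cells at 24 hpf) scored highest for progenitors. By the naming rule it had 6 markers of Müller glia among its top genes and 2 of progenitors. Those top genes included her12, her4.1, her4.4, both her4.2 copies, id1 and pcna. No cell at 24 hpf was named Müller glia, so the rule left out cells that need not be glial. The progenitor shares leave out the cells of unnamed clusters. No test of the shares was made, and an exact permutation of 2 libraries against 2 gives no two-sided p below 0.333.

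**Figure D1:**
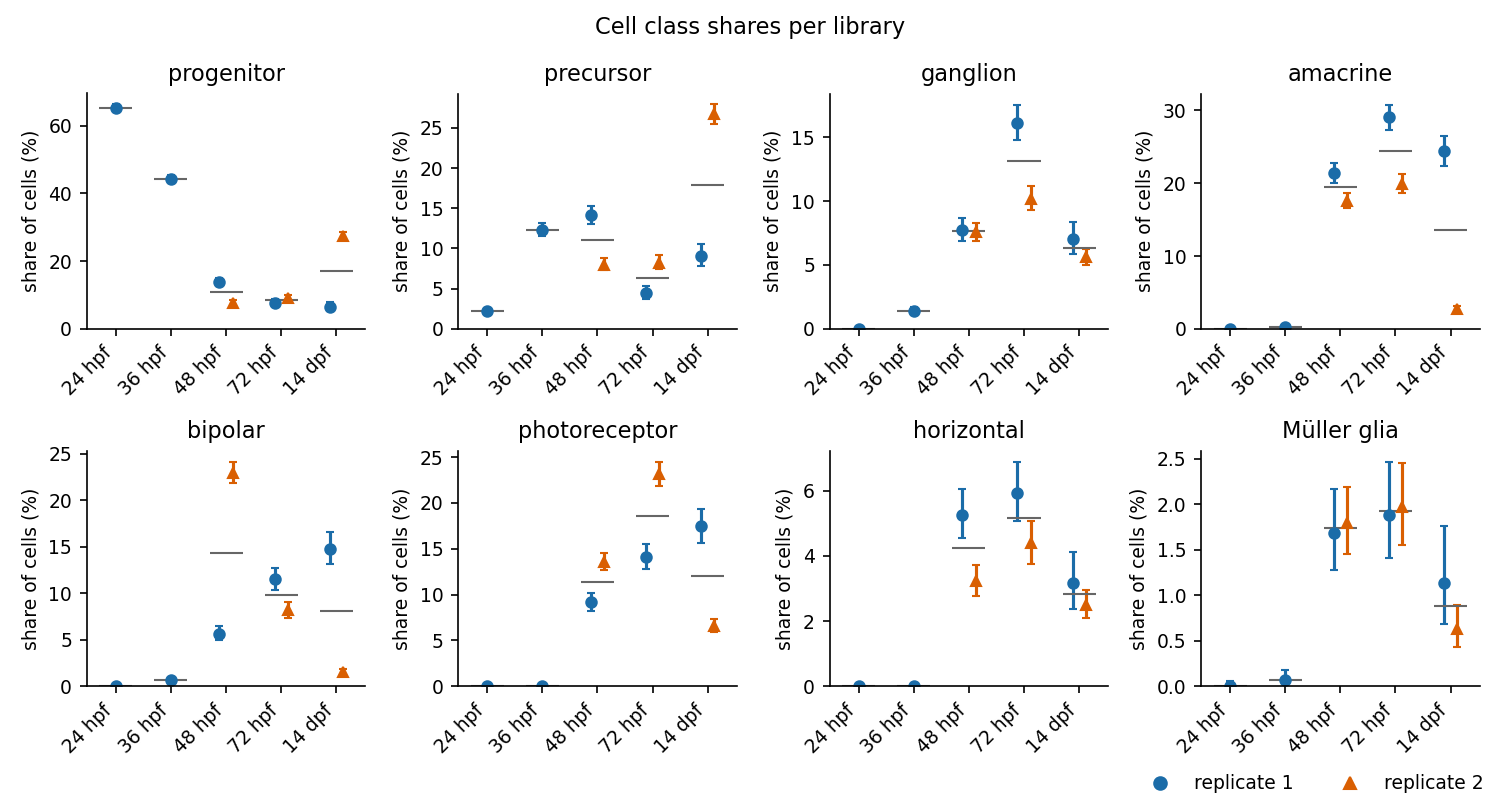
Share of cells in 8 retinal classes (percent of all cells kept in a library) by stage, with 1 point per library, exact 95% intervals as bars and the stage mean as a grey line. Progenitors stood at 65.3% at 24 hpf and 44.2% at 36 hpf, and 14 dpf replicates 1 and 2 stood apart at 6.56% and 27.4%.

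Neurogenic genes were higher in progenitors at 36 than at 24 hpf, and the lists of the cell cycle also had median ratios above 1, though smaller. The proneural factor atoh7, needed for ganglion cell birth, went from 0.689 to 26.0 counts per 1000000 UMIs (CPM), a ratio of 37.7 (95% exact Poisson interval 27.2 to 53.6). Over all cells atoh7 went from 2.59 to 86.6 CPM and in lens cells from 0.163 to 3.97 CPM, and the share of free RNA in these values was not measured. The ratio was 12.4 for neurod4 (10.9 to 14.1), 11.6 for foxn4 (9.83 to 13.8), 5.17 for ascl1a (4.80 to 5.56) and 1.62 for hes6 (1.54 to 1.70). The proneural and neurogenic list as a whole held 658 CPM at 24 hpf and 1222 CPM at 36 hpf, a ratio of 1.86 (1.82 to 1.89). The hairy-related repressor hes2.2 was at 10.4 and 377 CPM. Replication factor pcna was at 2370 and 2272 CPM, mki67 at 231 and 224 CPM, and ccnd1, a G1 cyclin, at 423 and 384 CPM. Genes of the retinal stem cell niche were lower at 36 hpf, with ratios of 0.685 for her9 (0.664 to 0.707), 0.723 for col15a1b (0.653 to 0.8) and 0.735 for fabp11a (0.713 to 0.757). The RNA-binding protein gene lin28a, a marker of early developmental timing, was at 9.09 and 1.62 CPM. The homeobox gene rx2 was at 14.7 and 12 CPM. Among the largest ratios downward were 0.129 for pdcd4b (a translation inhibitor), 0.183 for the Ras-like gene rasl11b, 0.223 for the small heat shock gene hspb1 and 0.234 for the anti-proliferative gene tob1b. Others were 0.248 for zbtb16a, 0.265 for the Notch target hey1 and 0.283 for klf6a. The proneural list had a median log2 ratio of 0.81 (22 genes), the neuronal cytoskeleton 0.65 (15 genes), G2/M and mitosis 0.43 (53 genes), the Notch pathway 0.39 (30 genes) and DNA replication 0.24 (52 genes). Each stood at the percentile of 100 among 10000 expression-matched random lists. Precursor markers stood there too, with a larger median of 1.64 (20 genes, 11 at least 2-fold higher), while precursors went from 2.25% to 12.4% of cells. At percentiles of 0.2 or below were the dorsal and temporal retina (-0.60), glycolysis (-0.55), dissociation and heat shock genes (-0.47) and stem cell genes (-0.43). So were the Wnt pathway (-0.39), Hedgehog, Fgf and Bmp response genes (-0.35) and eye field factors (-0.34). Lens crystallin genes led the upward ratios, from 0.103 to 53.7 CPM for crygm2d2, 0.258 to 74.3 CPM for crygm2d1 and 6.47 to 145 CPM for crybb1l1. These crystallins, whose copies are close to identical and uncertain one by one, took 0.215% of UMIs in progenitors, 0.318% in precursors and 0.328% in ganglion cells of the 36 hpf library, and 13.7% in its lens cells. With 1 library per stage no replicate check was possible, and the intervals cover counting error only.

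Progenitors of the 14 dpf margin lay nearest to those of 72 hpf. Over genes with a mean of at least 20 CPM, the root mean square difference of log2 CPM between 14 dpf and 72 hpf progenitors was 0.668 ± 0.047 (SD over the 4 pairs of libraries). It was 0.829 ± 0.086 for 48 hpf (4 pairs), 0.920 ± 0.073 for 36 hpf and 0.984 ± 0.019 for 24 hpf (2 pairs each). Pairs of the same stage differed by 0.714 at 14 dpf, 0.528 at 48 hpf and 0.368 at 72 hpf. The single pairs of 14 dpf and 72 hpf libraries ranged from 0.61 to 0.716, about the distance between the 14 dpf replicates. Of the embryonic stages, 24 hpf lay 0.615 from 36 hpf, 1.03 from 48 hpf and 0.921 from 72 hpf. Progenitors of 36 hpf also lay nearer to 72 hpf (0.782) than to 48 hpf (0.862). The distances thus did not follow the order of stages, and lying nearer to 72 than to 48 hpf was not particular to 14 dpf. No test was made of these distances. The cluster holding most progenitors was the same at 24 hpf (33.9% of them), 36 hpf (32.8%), 72 hpf (32.6% and 37.4%) and 14 dpf (40.9% and 44.9%), while at 48 hpf others led in replicate 1 (29.1%) and replicate 2 (28.5%).

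Between 48 and 72 hpf no single gene passed the test in progenitors. The proneural, G2/M and replication lists passed downward with the preset correlation only, and not with an estimated one (adjusted p = 0.411, 0.331 and 0.548 with an estimated correlation). The precursor markers otx2 (log2 fold -1.29 ± 0.31, SE), hes6 (-0.97 ± 0.26) and neurog1 (-1.81 ± 0.53) and the mitotic gene cdc20 (-0.71 ± 0.23) were not called. Nor were the stem cell genes col15a1b (1.17 ± 0.36) and fabp11a (0.79 ± 0.25). The proneural list (38 genes; 0 called, 0 adjusted over the list alone) passed downward by camera at adjusted p = 5.78e-13 (adjusted p = 0.411 with an estimated correlation). G2/M genes (54 genes) did so at 2.17e-07 (adjusted p = 0.331 with an estimated correlation) and replication genes (52 genes) at 8.04e-05 (adjusted p = 0.548 with an estimated correlation). Precursor markers (33 genes, 0 called) passed downward as well, at 1.43e-10 (adjusted p = 0.411 with an estimated correlation). Of the marker lists of other cells, 3 passed upward. Among them were those of the retinal pigment epithelium (RPE; 7 genes) at 1.08e-09 (adjusted p = 0.331 with an estimated correlation) and of Müller glia (44 genes) at 0.00132 (adjusted p = 0.556 with an estimated correlation). Glycolysis (24 genes, led by pgk1 at 1.08 ± 0.32) passed upward at 0.000183 (adjusted p = 0.423 with an estimated correlation). Dissociation and heat shock genes (46 genes; 9 up and 1 down adjusted over the list alone) passed upward at 2.67e-11 (adjusted p = 0.349 with an estimated correlation). Cone transducin subunit gene gngt2b, a photoreceptor gene, stood at 6.27 ± 1.31. The 9 phototransduction genes measured here passed upward beside it (6 up adjusted over the list alone; 4.59e-09, adjusted p = 0.331 with an estimated correlation). Of 8626 genes tested by edgeR, 0 passed, 544 had an unadjusted p under 0.05, and DESeq2 called 6 up and 2 down. Leaving out 72 hpf replicate 2 gave 6 calls, and fitting only the 4 libraries of these stages gave 4.

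Against 72 hpf, single genes such as cebpd, arg2 and tfr1b rose in progenitors of the 14 dpf margin. The C/EBP transcription factor gene cebpd rose by 4.60 ± 0.64 (log2, SE; n = 2 libraries per stage), arg2, a mitochondrial arginase, by 4.93 ± 0.60, and fabp7b, a brain-type fatty acid binding protein, by 5.06 ± 0.69. The transferrin receptor gene tfr1b, for iron uptake, rose by 2.60 ± 0.35, and the lens crystallin cryba4 by 3.32 ± 0.45 (each adjusted p = 0.0154). The prostaglandin D synthase gene ptgdsb.1 had 401 UMIs at 14 dpf and 1 at 72 hpf, a ratio of CPM of 135 (95% counting interval 24.0 to 5329; adjusted p = 0.0154). The gene ggctb, of glutathione turnover, fell by 1.85 ± 0.27 on the log2 scale (adjusted p = 0.0186). Among genes of the cell cycle and of progenitor identity fixed in advance, none of these was called, namely pcna (0.10 ± 0.26), mki67 (-0.57 ± 0.22), ccnd1 (0.27), rx2 (0.05), her9 (-0.18), col15a1b (-0.23) and fabp11a (-0.34). Among lists, G2/M genes (54 genes; 0 called, 7 down adjusted over the list alone) passed downward at adjusted p = 1.46e-12 (adjusted p = 0.237 with an estimated correlation), with g2e3 at -1.16 ± 0.23 and cenpf at -0.96. Notch pathway genes (36 genes, 0 called; notch1a at -0.70) passed downward at 0.00133 (adjusted p = 0.466 with an estimated correlation). Temporal competence factors (29 genes, 0 called; igf2bp1 at -0.82) did so at 0.034 (adjusted p = 0.466 with an estimated correlation). The proneural list (38 genes, 0 called) passed downward at 0.00597 and precursor markers (33 genes, 0 called) at 0.0351 (adjusted p = 0.689 and adjusted p = 0.727 with an estimated correlation). Dissociation and heat shock genes (46 genes; 1 up, 17 up adjusted over the list alone) passed upward at 1.04e-10 (adjusted p = 0.466 with an estimated correlation). Glycolysis (24 genes; 6 up and 1 down adjusted over the list alone; pdk2b at 2.22, eno3 at 1.16) followed at 0.00222 (adjusted p = 0.466 with an estimated correlation). The stem cell list (37 genes; 0 up, 1 down) did not pass (adjusted p = 0.733). Lens markers (9 genes; 3 up, 9 up adjusted over the list alone) passed upward at 2.06e-29 (adjusted p = 0.411 with an estimated correlation). So did Müller glia markers (44 genes; 3 up) at 0.0351 (adjusted p = 0.652 with an estimated correlation). Markers of amacrine cells (23 genes), bipolar cells (26 genes) and photoreceptors (35 genes), with 0 called, passed downward at 5.33e-06, 5.91e-05 and 8.59e-07 (each adjusted p = 0.466 with an estimated correlation). Those of RPE (7 genes) and horizontal cells (10 genes) did so at 0.0319 and 0.0407 (adjusted p = 0.466 and adjusted p = 0.563 with an estimated correlation). Phototransduction genes (9 genes; 7 down adjusted over the list alone) passed downward at 2.96e-05 (adjusted p = 0.466 with an estimated correlation). In all, 29 genes rose and 5 fell of 8626 (1125 at unadjusted p under 0.05; DESeq2 67 up, 21 down). The 34 calls became 6 without 72 hpf replicate 1, 2 without 72 hpf replicate 2, 300 without 14 dpf replicate 1 and 71 without 14 dpf replicate 2. None of the 7 called genes named here was called without 72 hpf replicate 2, and only arg2 and ptgdsb.1 were called without 72 hpf replicate 1. Fitting only the 4 libraries of these stages ended the calls of cebpd and fabp7b. At the finer clustering resolution fabp7b turned to -0.52, and with stronger integration of the libraries fabp7b, cebpd and ggctb were not called.

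Against 48 hpf, genes such as the mitotic cdc20 and g2e3 and the precursor factors otx2 and crx fell in progenitors of 14 dpf, and genes such as cebpd, arg2 and dusp5 rose. In 48 hpf replicates 1 and 2 and then 14 dpf replicates 1 and 2, the mitotic activator cdc20 was at 162, 181, 60 and 46.8 CPM (log2 fold -1.52 ± 0.24, adjusted p = 0.00729). The ubiquitin ligase g2e3 was at 116, 94.7, 33.4 and 25.6 CPM (-1.67 ± 0.24, adjusted p = 0.00494). The kinetochore gene cenpf fell by 1.31 ± 0.22 (adjusted p = 0.0106), the cyclin ccne2 by 1.4 ± 0.30 (0.026) and the histone mRNA-binding slbp by 1.02 ± 0.26 (0.0447). The photoreceptor and bipolar precursor factor otx2 was at 129 and 149 CPM at 48 hpf and 49.9 and 21.2 CPM at 14 dpf (-1.92 ± 0.32, adjusted p = 0.0106). The cone-rod factor crx was at 115 and 74.4 against 29.0 and 8.68 CPM (-2.40 ± 0.42, adjusted p = 0.011). The cell cycle inhibitor cdkn1ca fell by 2.2 ± 0.45 (adjusted p = 0.0223), and the neurogenic repressors her8a by 2.18 ± 0.45 (0.0229) and hes6 by 1.2 ± 0.27 (0.0294). The neuronal zinc finger gene myt1a fell by 2.1 ± 0.40 (0.0166) and the corepressor cbfa2t3 by 2.19 ± 0.37 (0.0108). The circadian repressor nfil3-5 fell by 1.99 ± 0.47 (0.0359), the neural factor sox3 by 2.46 ± 0.50 (0.02) and the tubulin tubb5 by 1.3 ± 0.31 (0.0384). Upward, cebpd went from 0.481 and 0.456 CPM to 110 and 289 CPM (8.94 ± 0.89, adjusted p = 0.00186). The arginase gene arg2 went from 3.61 and 1.6 to 172 and 46.8 CPM (5.43 ± 0.61, adjusted p = 0.00192) and fabp7b rose by 6.30 ± 0.74 (0.002). The MAP kinase phosphatase gene dusp5 rose by 5.34 ± 0.71 (adjusted p = 0.00356), the Yap target cyr61 by 3.49 ± 0.50 (0.00531) and the Polycomb gene cbx7a by 4.18 ± 1.02 (0.0398). Of the glycolytic genes, pdk2b rose by 4.76 ± 0.68 (0.00519), pkma by 1.57 ± 0.29 (0.0144) and eno3 by 1.5 ± 0.32 (0.0241). The cytokine signal inhibitor socs3a (ENSDARG00000025428) was at least 24.5-fold higher and the tissue factor gene f3a at least 19.6-fold higher, both with 0 UMIs at 48 hpf against a floor of 3 counts over the stage. The G protein regulator rgs5b had 1043 UMIs against 1 (ratio of CPM 490, counting interval 87.8 to 19390), and ptgdsb.1 again had 401 against 1 (ratio 189, 33.7 to 7466).

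Counted by list, G2/M genes split 0 up and 19 down of 54 (36 down adjusted over the list alone; set adjusted p = 2.99e-18, adjusted p = 0.134 with an estimated correlation). Proneural genes split 0 up and 8 down of 38 (1 up and 17 down adjusted over the list alone; 1.87e-11, adjusted p = 0.561 with an estimated correlation). Dissociation and heat shock genes split 20 up and 0 down of 46 (26 up adjusted over the list alone; 4.34e-18, adjusted p = 0.466 with an estimated correlation). Summed, this list took 1.28% and 2.98% of progenitor UMIs in 48 hpf replicates 1 and 2 and 3.55% and 2.76% in those of 14 dpf, so 48 hpf replicate 2 lay above 14 dpf replicate 2. Glycolysis split 8 up of 24 (11 up adjusted over the list alone; 2.54e-06, adjusted p = 0.484 with an estimated correlation). Yap and Taz targets split 2 up of 12 (4 up adjusted over the list alone; 0.0302, adjusted p = 0.484 with an estimated correlation). The stem cell list went both ways, with 4 up and 5 down of 37 (5 up and 5 down adjusted over the list alone), and did not pass (adjusted p = 0.459). Not called were pcna (-0.35 ± 0.26), mki67 (-0.76 ± 0.22), ccnd1 (-0.36), rx2 (0.28), her9 (0.43), col15a1b (0.94 ± 0.36) and fabp11a (0.45). Of neurogenic genes, atoh7 (-0.75), ascl1a (-0.64), foxn4 (-0.64) and neurod4 (-1.28 ± 0.44) were not called, nor was lin28a (-0.28), and nfia was too low to test. Markers of lens (9 genes, 9 up; 8.85e-17, adjusted p = 0.484 with an estimated correlation) and of Müller glia (44 genes, 10 up and 1 down; 0.000684, adjusted p = 0.561 with an estimated correlation) moved upward beside the stress genes. Those of precursors (33 genes, 5 down) and photoreceptors (35 genes, 3 down) passed downward at 1.64e-08 and 0.0103 (both adjusted p = 0.561 with an estimated correlation). Ribosomal protein genes took 38.0% of UMIs in the median cell of 14 dpf replicate 2 and 26.0% in replicate 1. Of 8626 genes, 389 rose and 149 fell. The 538 calls became 32 without 48 hpf replicate 1, 118 without 48 hpf replicate 2, 857 without 14 dpf replicate 1 and 257 without 14 dpf replicate 2. They were 174 in the largest progenitor cluster alone. Of the 28 called genes named here, cebpd, arg2, dusp5, rgs5b and ptgdsb.1 were called without each library in turn, and 5 were called without 48 hpf replicate 1. At the finer resolution otx2, crx, hes6, sox3, nfil3-5, tubb5, fabp7b and cbx7a were not called. In the largest cluster alone crx, sox3, cdc20, g2e3, cenpf, pkma and eno3 were not called. Stronger integration and joined unnamed clusters each ended the calls of her8a, slbp, nfil3-5 and cbx7a. Thinned sums ended those of slbp and eno3, the fit of 4 libraries that of slbp, and DESeq2 that of cbx7a.

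**Figure D2:**
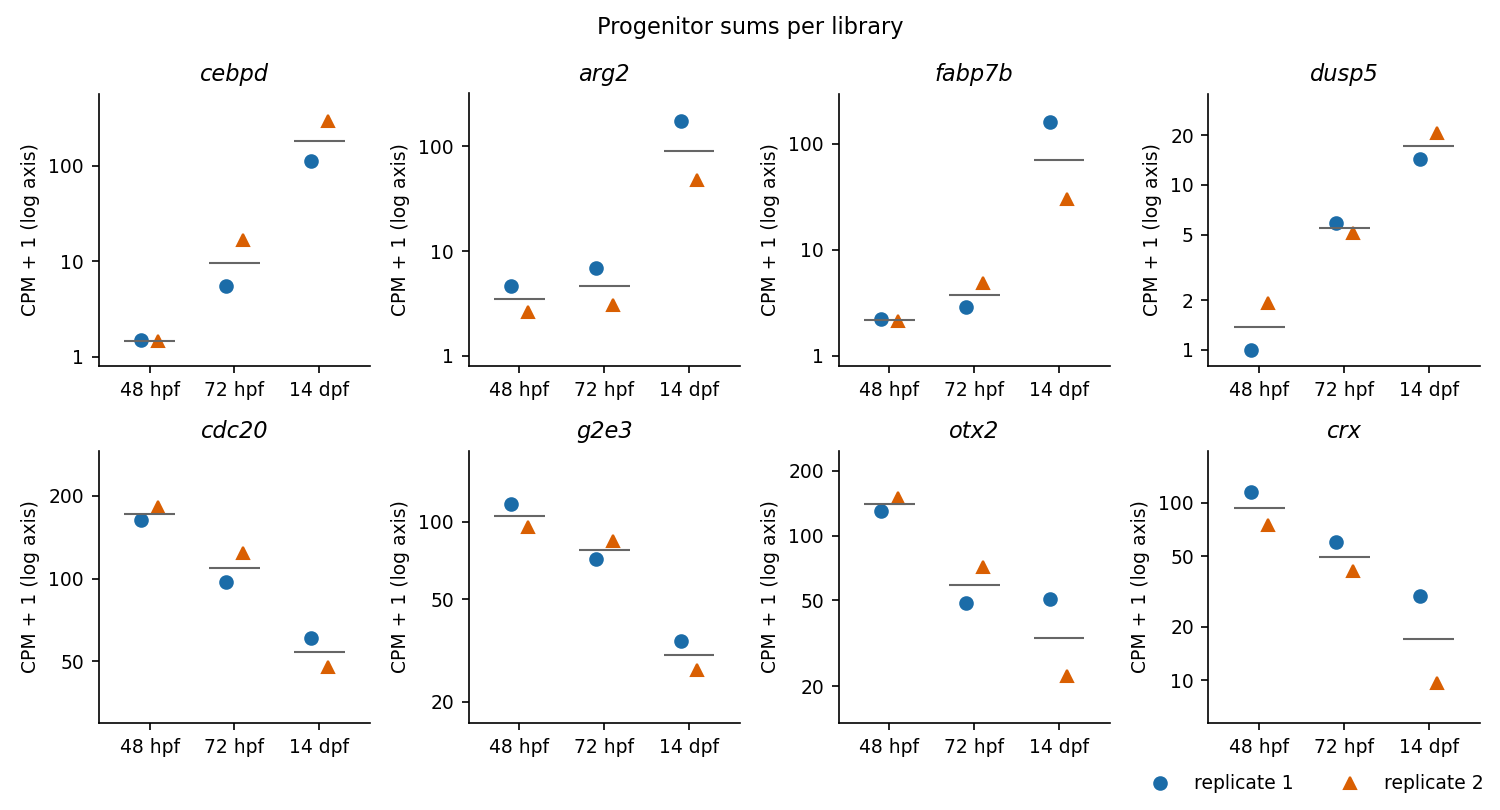
CPM + 1 (log axis) of 8 genes in progenitor sums by stage, with 1 point per library and the geometric mean of CPM + 1 as a grey line. Mitotic cdc20 and g2e3 stood at 60 and 33.4 CPM in 14 dpf replicate 1 against 162 and 116 CPM in 48 hpf replicate 1, while cebpd stood at 110 and 289 CPM at 14 dpf against under 1 CPM at 48 hpf.

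In neurogenic precursors, 2 genes separated the 14 dpf margin from 72 hpf. The translation repressor gene eif4ebp3l rose by 3.40 ± 0.40 on the log2 scale, from 8.02 and 6.57 CPM to 59.7 and 71.4 CPM. The gene crabp2a, whose protein binds retinoic acid inside cells, rose by 2.79 ± 0.33, from 17.2 and 20.3 CPM to 140 and 99.8 CPM (both adjusted p = 0.0204, n = 2 libraries per stage). Early eye field and stem cell genes had positive log2 folds without being called, among them zic2a (1.81 ± 0.38), zic2b (1.32 ± 0.31), nr2f5 (2.06 ± 0.48), mych (2.24 ± 0.51), rx2 (1.47) and fabp11a (1.69). The eye field list (32 genes; 4 up and 1 down adjusted over the list alone) passed upward at adjusted p = 0.000734 (adjusted p = 0.55 with an estimated correlation). The stem cell list (31 genes; 5 up and 2 down adjusted over the list alone) passed at 0.00862 (adjusted p = 0.564 with an estimated correlation). Notch genes (32 genes, 0 called; her4.1 at -1.92 ± 0.66 and nrarpa at -1.07) passed downward at 6.56e-06 (adjusted p = 0.524 with an estimated correlation). G2/M genes (54 genes, 0 called; ccnb1 at -0.91) did so at 4.84e-05 (adjusted p = 0.564 with an estimated correlation). Stress genes (38 genes; jun at 1.79 ± 0.35, junbb at 2.72 ± 0.53; 5 up adjusted over the list alone) passed upward at 3.55e-06 (adjusted p = 0.564 with an estimated correlation). Lens markers (6 genes, 0 called) passed upward too, at 1.28e-14 (adjusted p = 0.443 with an estimated correlation), and lens crystallins went from 8 and 6 CPM at 72 hpf to 200 and 58.3 CPM at 14 dpf. Markers of photoreceptors (34 genes), bipolar cells (27 genes) and RPE (6 genes) passed downward at 2.56e-08, 0.00055 and 1.18e-10. These were adjusted p = 0.524, 0.564 and 0.443 with an estimated correlation. Forebrain markers (9 genes) passed upward at 0.0268 (adjusted p = 0.564 with an estimated correlation). The proneural gene atoh7 (0.45) and the G1 cyclin ccnd1 (0.94) were not called. Of 7175 genes 2 passed (574 at unadjusted p under 0.05; DESeq2 20 up, 13 down). There were 6 calls without 72 hpf replicate 1, 141 without 14 dpf replicate 1 and 14 without 14 dpf replicate 2. Neither named gene was called without 72 hpf replicate 2 or at the finer clustering resolution. In turn, crabp2a was not called without 72 hpf replicate 1 or with stronger integration. One precursor cluster held 58.2% and 61.8% of precursors at 14 dpf, 53.7% in 48 hpf replicate 2 and 55.6% in 72 hpf replicate 1. Another led in 48 hpf replicate 1 and 72 hpf replicate 2 (50.5% each).

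Between 48 and 72 hpf, precursors showed 0 calls by edgeR among 7175 genes (236 at unadjusted p under 0.05; DESeq2 2 up, 1 down; 3 without 72 hpf replicate 2). The photoreceptor factors otx2 (-0.86 ± 0.34) and crx (-0.88 ± 0.36), the horizontal cell factor onecut1 (-0.73), the stress gene fosab (1.76 ± 0.44) and the late competence factor nfia (1.34 ± 0.70) were not called. The proneural list (40 genes) passed downward at adjusted p = 1.1e-05 (adjusted p = 0.599 with an estimated correlation). Temporal competence factors (26 genes; foxp4 at 0.59) passed upward at 0.0337 (adjusted p = 0.599 with an estimated correlation). Oxidative phosphorylation (74 genes) did so at 0.00458 (adjusted p = 0.735 with an estimated correlation) and synapse genes (13 genes; snap25b at 1.06) at 3.37e-08 (adjusted p = 0.599 with an estimated correlation). Phototransduction genes (10 genes; 5 up adjusted over the list alone; gngt2b at 5.26 ± 1.11) passed upward beside them at 7.29e-14 (adjusted p = 0.273 with an estimated correlation).

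The step from progenitor to precursor differed at 14 dpf from that at 48 and 72 hpf for single genes such as mcl1b, e2f3, cdkn1ca and copies of her4. The Notch targets her4.2 (ENSDARG00000094426) and her4.4 were lower in precursors than in progenitors at 14 dpf, with log2 differences of -1.41 ± 0.09 and -1.27 ± 0.05 (SD, n = 2). The differences were -0.12 ± 0.31 and -0.15 ± 0.21 in the embryonic libraries (n = 4). The fitted difference between the steps was -1.38 ± 0.17 for this her4.2 copy, -1.37 ± 0.18 for the copy ENSDARG00000056729 and -1.23 ± 0.15 for her4.4 (adjusted p = 0.00151, 0.00169 and 0.00151). Near-identical copies are uncertain one by one. Summed over 7 copies of the her4 and her15 families, counts went from 13610 CPM in progenitors to 9937 in precursors and from 2729 to 2052 in 14 dpf replicates 1 and 2. They were higher in precursors than in progenitors in 4 of 4 embryonic libraries. They went from 6912 to 8272 CPM and from 8209 to 14300 CPM at 48 hpf, and from 13290 to 18060 CPM and from 11130 to 16570 CPM at 72 hpf. The survival gene mcl1b (-1.36 ± 0.17, adjusted p = 0.00151) and the growth arrest gene gadd45ba (-1.64 ± 0.24, 0.00396) also had a lower difference at 14 dpf. So did the heat shock gene hsp70l (-0.95 ± 0.13, 0.00264), with copies close to identical too, and bckdk of amino acid breakdown (-1.26 ± 0.26, 0.041). In the other direction was zic2a (1.52 ± 0.25, adjusted p = 0.00692), a zinc finger gene of early eye patterning. The nuclear receptor nr2f5 (2.21 ± 0.34, 0.00416) and the S-phase activator e2f3 (1.78 ± 0.27, 0.00396) went with it. The cell cycle inhibitor cdkn1ca (1.65 ± 0.22, adjusted p = 0.0021) stepped up by 3.97 ± 0.23 at 14 dpf and by 2.41 ± 0.75 before. The bipolar factors vsx1 (1.29 ± 0.25, 0.0249) and otx2 (0.83 ± 0.16, 0.0229) stepped up more as well. So did the lipid transporter mfsd2ab (1.72 ± 0.30, 0.0125) and the phosphodiesterase subunit pde6g (1.69 ± 0.30, 0.0127). By mean CPM at 14 dpf against the embryonic libraries, otx2, cdkn1ca, mfsd2ab and pde6g were lower in progenitors and not higher in precursors. For otx2 these were 35.5 against 99.1 and 364 against 516 CPM. Precursor levels of vsx1, zic2a, nr2f5 and e2f3 were higher at 14 dpf. Those of mcl1b (95 against 88) and gadd45ba (56 against 59) were similar, with higher progenitor levels (115 against 46 and 83 against 33).

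By list, Notch genes had 0 up and 7 down of 36 (3 up and 9 down adjusted over the list alone) without passing (adjusted p = 0.0877). Their median log2 difference was 0.27, above 0, while the test ran downward. Proneural genes had 3 up of 41 (10 up adjusted over the list alone; 8.49e-07, adjusted p = 0.615 with an estimated correlation). Eye field factors had 2 up of 36 (11 up adjusted over the list alone; 1.06e-06, adjusted p = 0.615 with an estimated correlation). G2/M genes had 0 called of 54 and passed upward at 8.49e-07, and glycolysis had 0 of 25 and passed downward at 0.00241 (both adjusted p = 0.615 with an estimated correlation). Stem cell genes had 0 of 36 (15 up adjusted over the list alone; 0.00238, adjusted p = 0.615 with an estimated correlation). Dissociation and heat shock genes had 3 down of 48 (2 up and 9 down adjusted over the list alone; 0.0013, adjusted p = 0.615 with an estimated correlation). The step did not differ by the test for pcna (-0.03), atoh7 (0.73), rx2 (1.32), mycn (0.82) and ccnd1 (0.78). Of 8853 genes, 31 passed upward and 15 downward (976 at unadjusted p under 0.05; DESeq2 13 up, 11 down). The 46 calls became 26 without 72 hpf replicate 1, 17 without 72 hpf replicate 2, 109 without 48 hpf replicate 2, 220 without 14 dpf replicate 1 and 18 without 14 dpf replicate 2. They were 9 with 72 hpf alone as the reference. Of the 15 called genes named here, 5 were called without each library in turn, namely both her4.2 copies, her4.4, mcl1b and hsp70l. The her4 and hsp70l calls were lost when the unnamed clusters were joined to their best-scoring class, and with stronger integration. So were those of e2f3 and pde6g, which were also lost with thinned sums and at the finer resolution. With 72 hpf alone as the reference, only e2f3, gadd45ba and the her4 copies of those named were called. DESeq2 did not call pde6g, vsx1 and bckdk. Among the unnamed clusters, one led by her12 and her4.1 held 8.72% of cells at 24 hpf and 1.55% and 5.23% at 14 dpf. In the largest cluster of each class alone, cdkn1ca and otx2 turned to -0.07 and -1.51.

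**Figure D3:**
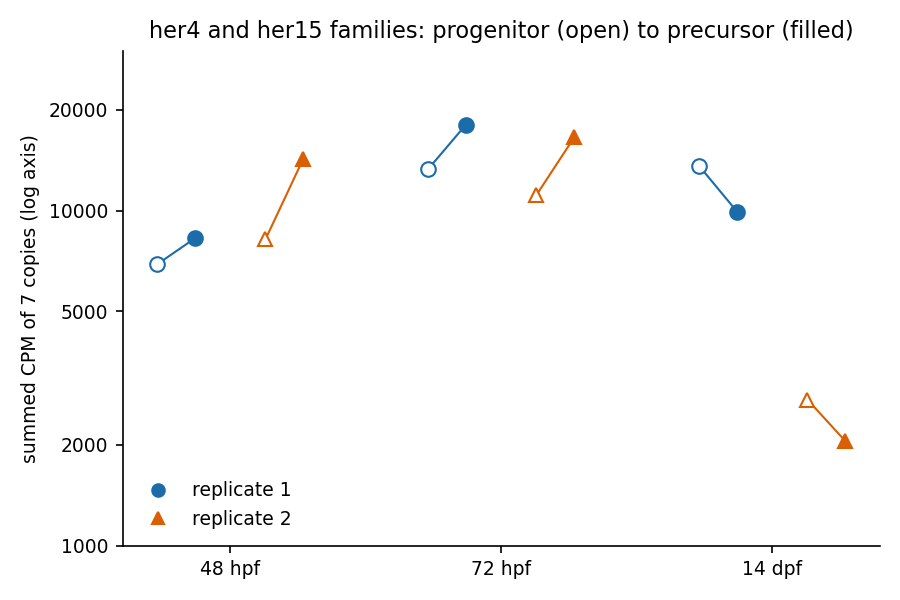
Summed CPM of 7 copies of the her4 and her15 families in progenitors (open points) and precursors (filled points) of each library at 48 hpf, 72 hpf and 14 dpf. The precursor sum was higher in the 4 embryonic libraries (8272 against 6912 CPM in 48 hpf replicate 1) and lower in the 2 libraries of 14 dpf (9937 against 13610 and 2052 against 2729 CPM).

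In photoreceptors between 48 and 72 hpf, genes such as the cone phototransduction genes opn1lw2 and gnat2 rose, and genes such as the mitotic top2a and cdca8 fell. In 48 hpf replicates 1 and 2 and then 72 hpf replicates 1 and 2, the red cone opsin opn1lw2 was at 101, 93.9, 5520 and 3270 CPM (log2 fold 5.46 ± 0.33). The transducin subunit gngt2b was at 265, 284, 9350 and 5430 CPM (4.71 ± 0.34) and the cone arrestin arr3a at 128, 66.5, 2540 and 1990 CPM (4.55 ± 0.33; each adjusted p = 0.00856, n = 2 libraries per stage). Cone transducin gnat2 and its partner gnb3b rose by 6.79 ± 0.80 and 6.78 ± 0.79 (both adjusted p = 0.0204), and the phosducin gene pdcb, a transducin regulator, by 6.79 ± 0.62 (0.0124). Green opsin opn1mw1 had 7418 UMIs at 72 hpf and 2 at 48 hpf (ratio of CPM 3557, 95% counting interval 984 to 29380), with copies of opsin genes uncertain one by one. The gene rgs9a, which speeds recovery from light, had 496 and 3 UMIs (ratio 159, 54.0 to 772), and the cone exchanger slc24a2 had a ratio of 118 (32.2 to 976). At the ribbon synapse, cplx4a rose by 4.89 ± 0.57 (adjusted p = 0.0204) and sv2ba by 3.57 ± 0.44 (0.023). The glycolytic enzymes aldocb (1.94 ± 0.23, 0.0212), gpia (1.75 ± 0.25, 0.0321) and pfkpa (3.17 ± 0.53, 0.0453) rose. The chromosome passenger gene cdca8 fell by 2.17 ± 0.28 (adjusted p = 0.026), the cohesin gene cdca5 by 2 ± 0.27 (0.0281), topoisomerase top2a by 1.98 ± 0.29 (0.0328) and importin kpna2 by 1.94 ± 0.24 (0.0228). The spindle gene ska1 fell by 2.02 ± 0.31 (0.0373), the helicase pif1 by 2.09 ± 0.30 (0.032), the kinase gene mibp by 2.07 ± 0.30 (0.032) and cenpf by 1.84 ± 0.25 (0.0281). The precursor factor olig2 (-3.02 ± 0.70) and ccnd1 (-1.34) were not called.

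By list, phototransduction genes split 19 up and 0 down of 42 (28 up and 1 down adjusted over the list alone; set adjusted p = 2.77e-46, adjusted p = 0.39 with an estimated correlation). G2/M genes split 0 up and 23 down of 53 (50 down adjusted over the list alone; 4.68e-52, adjusted p = 0.363 with an estimated correlation). Synapse genes split 5 up of 20 (12 up adjusted over the list alone; 3.21e-13, adjusted p = 0.39 with an estimated correlation), and glycolysis 3 up of 23 (17 up adjusted over the list alone; 2.76e-12, adjusted p = 0.39 with an estimated correlation). Replication genes (45 genes, 0 called, 9 down adjusted over the list alone; rrm1 at -1.76) passed downward at 6.03e-09 (adjusted p = 0.326 with an estimated correlation). Progenitor markers (52 genes, 14 down) did so at 8.39e-23 (adjusted p = 0.318 with an estimated correlation). Oxidative phosphorylation (78 genes, 0 called) passed upward at 1.77e-07 (adjusted p = 0.844 with an estimated correlation). Of 8297 genes, 105 rose and 40 fell. The 145 calls became 1180 without 48 hpf replicate 1, 993 without 48 hpf replicate 2, 59 without 72 hpf replicate 1 and 83 without 72 hpf replicate 2. They were 5 in the largest photoreceptor cluster alone, which held 44.5% and 45.2% of photoreceptors at 48 hpf and 60.8% and 68.0% at 72 hpf. There, gnat2, gnb3b, opn1mw1, sv2ba, aldocb, gpia, pfkpa, top2a, cdca5, kpna2 and mibp were not called, and rgs9a, slc24a2, pdcb, cplx4a, cdca8, pif1, ska1 and cenpf were not tested. The 8 falling genes named here and aldocb, gpia and pfkpa were not called when either 72 hpf library was left out, while 11 of the 22 named were called without each library in turn. At the finer resolution 7 of the 8 falling genes (all but mibp) and pfkpa were not called.

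**Figure D4:**
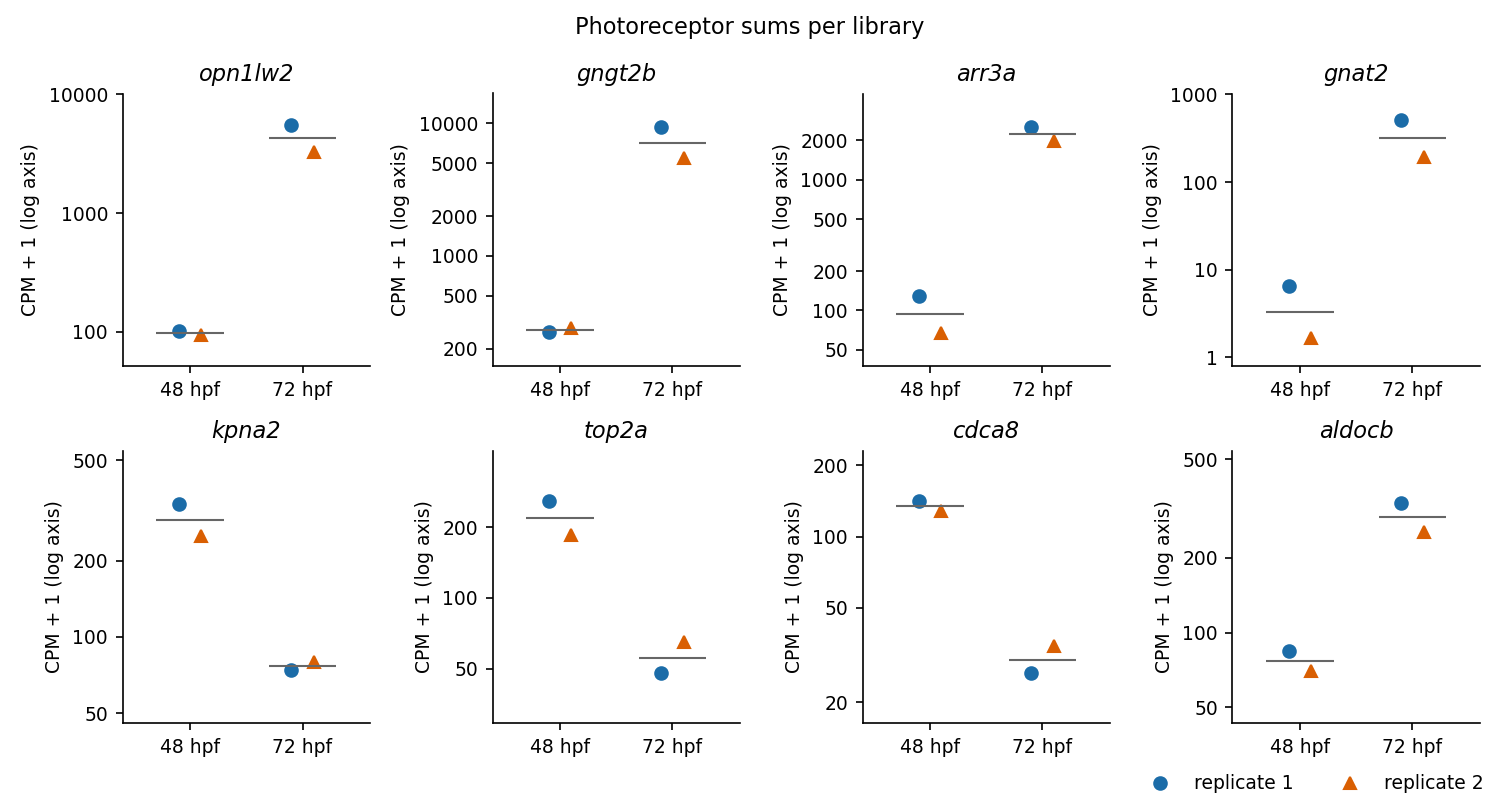
CPM + 1 (log axis) of 8 genes in photoreceptor sums of 48 and 72 hpf, with 1 point per library and the geometric mean as a grey line. Red opsin opn1lw2 stood at 101 and 93.9 CPM at 48 hpf and 5520 and 3270 CPM at 72 hpf, and top2a at 258 and 185 CPM and 46.8 and 63.9 CPM.

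In amacrine cells between 48 and 72 hpf, genes such as the synapse organizer cbln1 and the immediate early gene fosb rose. The cerebellin cbln1, a synapse organizer, rose by 6.31 ± 0.86, and the glycine receptor gene glra3 by 6.08 ± 0.82 (both adjusted p = 0.0366). Its partner glrbb rose by 3.55 ± 0.57, the active zone gene rims2a by 2.85 ± 0.46 and the septin sept9b by 6.40 ± 1.02 (each adjusted p = 0.0406). A second cerebellin, cbln2b, had a ratio of CPM of 333 (95% counting interval 59.3 to 13180). The immediate early genes fosb (5.30 ± 0.46, adjusted p = 0.0101) and nr4a1 (5.14 ± 0.70, 0.0366) rose, as did dusp5 (4.15 ± 0.59, 0.0366). The activity-dependent factor npas4a had 689 UMIs at 72 hpf and 1 at 48 hpf (ratio 739, 132 to 29240). Photoreceptor genes rose beside them, with gngt2b at 5.64 ± 0.82 (0.0366), opn1lw2 at least 107-fold higher (300 UMIs against 0, floor of 3 counts over the stage) and arr3a at a ratio of 161 (28.4 to 6398). Synapse genes split 6 up and 0 down of 53 (45 up adjusted over the list alone) and passed at 1.64e-32, and dissociation and heat shock genes 7 up of 42 (12 up adjusted over the list alone) at 4.71e-08. Phototransduction genes split 4 up of 15 (8 up adjusted over the list alone) at 3.14e-11, and each of these lists had adjusted p = 0.491 with an estimated correlation. Glycolysis (24 genes, 0 called, 16 up adjusted over the list alone; eno2 at 3.02, aldocb at 2.82) passed upward at 4.89e-10 and the neuronal cytoskeleton (45 genes, 0 called; tubb2 at 3.27, stmn2a at 2.46) at 4.34e-05 (adjusted p = 0.491 with an estimated correlation for both). Proneural genes (41 genes, 0 called; gadd45gb.1 at -1.74) passed downward at 7.01e-05 and Notch genes (26 genes, 0 called; lfng at -1.49) at 0.00128 (adjusted p = 0.491 with an estimated correlation for both). Of 8242 genes, 54 rose and 0 fell by edgeR (1264 at unadjusted p under 0.05; DESeq2 331 up, 13 down). The calls became 92 without 48 hpf replicate 1, 496 without 48 hpf replicate 2, 110 without 72 hpf replicate 1 and 1306 without 72 hpf replicate 2. The genes glrbb and rims2a were not called without 48 hpf replicate 1. With stronger integration, npas4a, cbln2b, sept9b, glrbb and rims2a were not called. One amacrine cluster led in replicate 1 of both stages (39.9% and 44.9% of amacrine cells) and another in replicate 2 (36.6% and 34.6%). In amacrine cells, dissociation and heat shock genes took 2.21% and 7.45% of UMIs in 48 hpf replicates 1 and 2, and 5.64% and 5.37% at 72 hpf.

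In ganglion cells between 48 and 72 hpf, genes such as the immediate early nr4a1, the receptor gene glra3 and the glycolytic pkma rose. The immediate early genes nr4a1 (4.96 ± 0.49, adjusted p = 0.000962), fosb (4.47 ± 0.50, 0.00163), npas4a (5.93 ± 0.84, 0.00529) and fosab (3.63 ± 0.47, 0.00425) rose. So did the stress gene gadd45ba (2.32 ± 0.33, 0.00529) and the G protein regulator rgs16 (4.59 ± 0.82, 0.0133). The calcium buffer gene pvalb6 rose by 4.48 ± 0.90 (adjusted p = 0.0235), the receptor genes glra3 by 3.54 ± 0.56 (0.00621) and gabrb2 by 3.09 ± 0.61 (0.0203), and the synaptic vesicle gene syn2a by 1.76 ± 0.34 (0.0194). Glycolytic pkma (2.28 ± 0.38, 0.00762), aldocb (2.52 ± 0.42, 0.00813) and pfkpa (2.07 ± 0.42, 0.023) and the respiratory chain gene ndufa4 (2.02 ± 0.33, 0.00659) rose. The homeobox gene barhl1a fell by 1.91 ± 0.44 (adjusted p = 0.0396), ahcy of the methylation cycle by 1.88 ± 0.40 (0.0285) and the elongation factor eef1da by 1.55 ± 0.35 (0.0348). Photoreceptor genes rose beside these, with gngt2b at 295 UMIs against 3 (ratio 112, 95% counting interval 37.9 to 546), opn1lw2 at a ratio of 47.8 (16.0 to 235) and arr3a at least 29.2-fold higher (77 UMIs against 0). Synapse genes split 8 up of 49 (28 up adjusted over the list alone) and passed at 3.93e-18, and glycolysis 7 up of 22 (15 up adjusted over the list alone) at 8.24e-13. Dissociation and heat shock genes split 8 up of 42 (14 up adjusted over the list alone) at 5.54e-12 and phototransduction 3 up of 8 (5 up adjusted over the list alone) at 1.29e-08. Notch genes (25 genes, 0 called, 4 down adjusted over the list alone) passed downward at 9.66e-05. Each of these lists had adjusted p = 0.38 with an estimated correlation. Of 7318 genes, 177 rose and 3 fell. The 180 calls became 2 without 72 hpf replicate 1, 509 without 48 hpf replicate 1 and 557 without 48 hpf replicate 2. Of the 20 called genes named here, nr4a1 and fosb were called without 72 hpf replicate 1, and eef1da was not called without 72 hpf replicate 2. DESeq2 did not call rgs16 (adjusted p = 0.406).

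Bipolar cells, the excitatory interneurons, had 0 calls by edgeR among 4463 genes between 48 and 72 hpf (205 at unadjusted p under 0.05; DESeq2 11 up, 1 down). The glucose transporter slc2a3a (3.14 ± 0.75), the synaptic vesicle gene vamp1 (2.52 ± 0.70), fosab (1.91 ± 0.38), otx2 (-1.37), the kinetochore gene spc25 (-1.58) and gngt2b (5.68 ± 0.83) were not called. Glycolysis (16 genes) passed upward at adjusted p = 1.04e-09, oxidative phosphorylation (75 genes; ndufa1 at 0.95) at 5.17e-08 and synapse genes (16 genes) at 1.66e-05. G2/M genes (18 genes) passed downward at 1.08e-08 and proneural genes (36 genes) at 6.6e-06, and each of these lists had adjusted p = 0.664 with an estimated correlation. Without single libraries the calls were 88 (48 hpf replicate 1), 184 (48 hpf replicate 2), 6 (72 hpf replicate 1) and 121 (72 hpf replicate 2).

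Cone, RPE and lens RNA was measured across the retinal classes. In the 72 hpf replicates 1 and 2, arr3a stood at 2540 and 1990 CPM in photoreceptors and 27.9 and 9.37 CPM in progenitors. It stood at 28.3 and 14.0 CPM in amacrine cells, 28.4 and 14.6 CPM in ganglion cells and 37.2 and 17.2 CPM in bipolar cells. Photoreceptor markers passed upward from 48 to 72 hpf in amacrine (2.67e-05), ganglion (0.000245) and bipolar cells (8.55e-08). These were adjusted p = 0.491, 0.456 and 0.664 with an estimated correlation. RPE genes went from 22.0 and 25.6 CPM in ganglion sums of 48 hpf to 184 and 130 CPM at 72 hpf and from 14.8 and 9.8 to 247 and 84.9 CPM in bipolar cells. In amacrine cells they took 0.0019% and 0.0009% of UMIs at 48 hpf and 0.0137% and 0.007% at 72 hpf. RPE markers passed upward over this step in precursors (1.04e-15), photoreceptors (5.03e-06), amacrine cells (7.1e-07) and ganglion cells (0.000135). These were adjusted p = 0.131, 0.432, 0.491 and 0.38 with an estimated correlation. Lens crystallins took 0.0215% and 0.0083% of progenitor UMIs in 14 dpf replicates 1 and 2, 0.0269% and 0.0094% of amacrine UMIs, and 0.0019% and 0.0002% of progenitor UMIs at 48 hpf. In 14 dpf replicates 1 and 2 cebpd stood at 110 and 289 CPM in progenitors and 212 and 352 CPM in lens cells. In Müller glia it stood at 410 and 164 CPM, with 19 cells in replicate 1, too few for the class sums compared elsewhere. In amacrine cells it stood at 4.54 and 6.43 CPM. In 72 hpf replicates 1 and 2 it stood at 91.1 and 59.6 CPM in Müller glia and 4.47 and 15.8 CPM in progenitors. Over all cells, dissociation and heat shock genes took 1.69% of UMIs in 48 hpf replicate 1 and 6.17% in replicate 2, 5.05% and 4.71% at 72 hpf, and 6.27% and 3.61% at 14 dpf. Across the 10 edgeR comparisons, 90 of 190 function list tests passed with the preset correlation, of which a part is named, and 0 with an estimated one.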

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

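The tests below of dissociation stress, of free RNA and of photoreceptor maturity were chosen only after the result was seen, while those of the summed her4 and her15 copies and of a wrong stage label were written before their results. The largest-cluster and joined-cluster settings were chosen after the data, and their counts of calls, were seen, but what they would show for her4 and her15 was written before those values were seen. The step from progenitor to precursor differed between 14 dpf and the embryonic stages by an interaction test for 46 genes (edgeR), which is why the genes named in this paragraph were singled out. The difference in log2 units was 1.78 for e2f3, 1.72 for mfsd2ab, 1.69 for pde6g, 1.65 for cdkn1ca and 1.52 for zic2a. It was -1.64 for gadd45ba, -1.38 and -1.37 for the her4.2 copies ENSDARG00000094426 and ENSDARG00000056729, -1.36 for mcl1b, -1.26 for bckdk and -1.23 for her4.4.

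Summed over their copies, the her4 and her15 genes fell from progenitors to precursors at 14 dpf (log2 differences of -0.45 and -0.41). They rose over this step in the 4 embryonic libraries (0.26 to 0.8). The difference between the 14 dpf and embryonic steps had a median of -1.17 over the 7 called copies. Unequal splitting of reads between near-identical copies as the whole cause is argued against by their summed counts, whose difference was -0.95 (-0.97 and -0.93 in the 2 libraries of 14 dpf, against the mean of the 4 embryonic libraries). Clusters led by her4.1 and her12 that were kept out of the named classes remain a candidate explanation, since the median was -0.35, with 0 of 7 called, when they were joined to their best-scoring class, and -2.2, with 7 of 7 called, in the largest cluster of each class alone. These values point both ways, so the share of the pattern owed to the choice of clusters stays open. A difference between post-embryonic and embryonic neurogenesis, the sort, the transgene and the sampled region also stay open, untested.

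Of the dissociation and heat shock list, 20 members were called higher in 14 dpf than in 48 hpf progenitors, with a median log2 fold of 2.78. The list as a whole took 1.28% and 2.98% of progenitor UMIs at 48 hpf and 3.55% and 2.76% at 14 dpf, so the replicates overlapped between the stages. Free RNA in the droplets as the whole source is argued against, since 0 of these 20 members lay under 25% of their all-cell level in both 14 dpf progenitor sums. The check is a weak one, since the members were chosen for being called in progenitors. Genes of this list such as hsp70l and jun were also present in all retinal classes of 14 dpf. A part from free RNA is therefore not excluded. Stress acting on all cells of a library could account for part of it, since the same members had medians of 1.35 in amacrine cells (the lowest), 1.42 in bipolar cells, 1.40 in ganglion cells and 1.77 in photoreceptors, on both sides of the level set for the decision. Over single pairs of libraries these medians ran from 1.09 to 1.89, 0.34 to 1.91, 0.65 to 1.5 and 0.82 to 1.92 in that order. Outside these 4 classes, the median was 2.1 in precursors and 2.21 in horizontal cells. The members were chosen for being called in progenitors, which raises the progenitor median and the level set from it. Lower medians in other classes therefore cannot decide whether stress acted on all cells alike, though the same members had medians above 0 in each of them. The sort and the stage are confounded, and a response of older progenitors themselves stays open as untested.

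The class shares of 14 dpf replicate 1 lay nearer to those of the unsorted 72 hpf libraries than to those of replicate 2, with 24.4% amacrine cells against 2.67%. A 72 hpf library with a wrong label is argued against by genes raised in replicate 2 over 72 hpf, chosen without replicate 1. Over 5 class sums, in which a gene can recur, 55 of 68 entries (80.9%) also exceeded both 72 hpf libraries in replicate 1. The lowest share was 66.7% in precursors (6 of 9), and progenitors had 4 of 5, few genes in each. Older neurons from outside the growing margin are a candidate explanation, since phototransduction genes took 6.14 times the share of photoreceptor UMIs in replicate 1 as in replicate 2. That ratio compares the 14 dpf replicates only. In photoreceptors of replicate 1, opn1lw2, arr3a and gngt2b were at 3320, 2140 and 2940 CPM. In 72 hpf replicates 1 and 2 they were at 5520 and 3270, 2540 and 1990, and 9350 and 5430 CPM. These genes thus did not stand above both 72 hpf libraries, and photoreceptors older than those of 72 hpf were not shown. The sort for a reporter of proliferating cells works against older neurons, and how they would have passed it was not tested. Whether the sort, the dissection or the animals differed between the 14 dpf replicates was not tested.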

How the results depend on the processing

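Stronger integration, joined unnamed clusters and the largest cluster alone were tests chosen only after the data were seen, and the other alternatives were planned. Direction was checked only for values called in the main fit or in the alternative. Of the values of single named genes under all alternatives, 5376 stayed on their side of the threshold and 372 came to pass it. The 5376 include genes that were not called in the main fit and stayed uncalled. Another 234, all of genes called in the main fit, no longer passed the threshold, and 3 changed sign. These were fabp7b in progenitors of 14 dpf against 72 hpf (-0.52 at resolution 2) and, for the step from progenitor to precursor in the largest clusters alone, cdkn1ca (-0.07) and otx2 (-1.51), and the cause was not tested.

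Counts of called genes moved as follows, with the cause not tested unless stated. For progenitors of 72 against 48 hpf (0 calls), DESeq2 gave 8, no low-count filter 160, the largest cluster 1, the 4 libraries alone 4, and leaving out single libraries 0 to 6. For 14 dpf against 72 hpf (34), DESeq2 gave 88, no filter 474, stronger integration 18, the 4 libraries alone 22, and leave-one-out fits 2 to 300. For 14 dpf against 48 hpf (538), no filter gave 1087, resolution 2 gave 330, the largest cluster 174, and leave-one-out fits 32 to 857. In precursors of 72 against 48 hpf (0), DESeq2 gave 3, no filter 53, and leave-one-out fits 0 to 3. In precursors of 14 dpf against 72 hpf (2), DESeq2 gave 33, no filter 231, thinned sums 4, resolution 2 gave 0 (694 at unadjusted p under 0.05), joined clusters 97, the 4 libraries alone 5, and leave-one-out fits 2 to 141. For the interaction (46), DESeq2 gave 24, no filter 189, stronger integration 28, joined clusters 167, 72 hpf alone as the reference 9, and leave-one-out fits 17 to 220.

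In photoreceptors (145), DESeq2 gave 352, no filter 774, resolution 2 gave 74, the largest cluster 5, and leave-one-out fits 59 to 1180. In amacrine cells (54), DESeq2 gave 344, no filter 987, thinned sums 165, at least 800 genes per cell 184, doublets kept 200, stronger integration 16, the largest cluster 283, and leave-one-out fits 92 to 1306. In bipolar cells (0), DESeq2 gave 12, no filter 157, and leave-one-out fits 6 to 184. In ganglion cells (180), no filter gave 430, and leave-one-out fits 2 to 557. Fits without the filter tested 14942 to 19901 genes in place of 4463 to 8853. Leaving out a library left 1 sample in its stage, which was assumed to vary like the other stages. In the comparison of 14 dpf with 48 hpf progenitors, the median log2 fold over all genes was 0.115 for DESeq2 over 18916 genes and -0.01 for edgeR over 8626, and in 14 dpf against 72 hpf precursors 0.101 and 0.013. The function list tests that passed went from 90 to 0 with an estimated correlation.

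The share of progenitors was 59.6% at resolution 2 and 56.0% with stronger integration at 24 hpf (65.3% as reported), and 38.6% and 41.5% at 36 hpf (44.2%). With 1 replicate left out it was 7.69% to 13.8% at 48 hpf, 7.78% to 9% at 72 hpf and 6.56% to 27.4% at 14 dpf. The 36 to 24 hpf ratio of the proneural sum (1.86) was 1.81 with at least 800 genes per cell, 1.98 with doublets kept and 1.92 at resolution 2. The distance of 14 dpf from 72 hpf progenitors was 0.599 over genes of at least 100 CPM (0.668 over genes of at least 20 CPM). No paired analysis was possible because replicate numbers carry no pairing between stages.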
